A study of Physcomitrium patens with 8 samples.

How the data were processed

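RNA-seq libraries of the moss Physcomitrium patens (Gransden strain) were analysed. The tissue was chloronemata, the green filaments that grow first from a moss culture, 6 days after subculture. There were 8 libraries, 1 for each pairing of 2 genotypes with 4 conditions. The genotypes were wild type (WT) and the line labelled PpanrKO (KO below). The conditions were untreated control, ABA, mannitol and dehydration. Per the labels' protocols, ABA (1e-05 M) and mannitol (10% w/v) acted for 1 h on tissue moved with its cellophane onto soaked paper, whereas dehydration took place in a desiccator over saturated salt until 70% of the fresh weight was lost. No mock transfer of the control tissue is described in the sources used here.

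Per the labels, RNA of 3 biological replicates was pooled before each library was made, polyadenylated RNA was selected and cDNA was primed at random. Each group is therefore 1 library, and the spread between the pooled cultures was not measured. The submitters' processing notes name FastQC, Trimmomatic, TopHat2, SAMtools and bedtools, with no versions. How the authors normalized the values is not given in the sources used here, nor is whether strand was used in counting.

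The deposited abundance signal is 1 normalized value per gene and library for 26610 genes. Within each library every value was a whole multiple of 1 step, within 0.01 read, so the deposited signal is the read count times 1 factor per library, with no correction for gene length. Whole reads were recovered by dividing by that step, and 100% of the values came out whole. The recovery was tested on simulated data, where none of 212880 values was missed. The recovered totals ran from 22516957 to 38767634 reads per library. At this depth counting error is small for abundant genes and large for genes with a handful of reads. Named genes are given with exact 95% intervals of the ratio of their reads, conditional on the sum. These intervals, and the limits given where a library had 0 reads, cover counting error only, because reads amplified by PCR are not independent molecules and each group has 1 library. A fold given as "at least" is the exact 95% limit of the ratio. Putting 3 reads in place of 0 gives a larger fold, as with 101203 against 82303 for Phpat.003G115800 with ABA.

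Gene positions are those of the deposited gene models of build V3.0 (Phytozome v10), which give the start and end of each gene and the older V1.6 model for 18716 genes, but no exons. The files pair the gene IDs with no names, and the RefSeq gene table at hand, of another assembly, shared 0 IDs with them. The 29 gene lists fixed before the data were examined (such as late embryogenesis abundant proteins, ABA signalling and photosynthesis) were therefore not applied, and no gene is named by function. The naming rule for this case, also fixed beforehand, was the 2 IDs with the largest and the 2 with the smallest log2 difference in each comparison. Genes named outside that rule are marked as chosen after their values were seen.

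Differences are on the log2(value + 10) scale, which understates the change of low genes. Genes with a mean of at least 20 normalized reads over the 8 libraries were kept (19821 genes, with 6789 left out). Comparisons of 2 libraries have no test. They are described by the number of genes at least 4-fold apart, and every such count describes these libraries. The KO response of genes picked in WT was read against the KO control, so the picked and the read values share no library. Picked genes lie closer to 0 in any second pair of libraries, so the reverse pick, from KO to WT, is also given.

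A test was possible only for effects that repeat across the crossed factor. All 8 libraries were fitted with limma (trend in intensity) as treatment plus genotype, with 3 residual degrees of freedom, and p-values were two-sided and Benjamini-Hochberg adjusted at 0.05. The residual of that fit holds the genotype-by-treatment difference together with the noise, and that difference itself was not tested. edgeR's quasi-likelihood test on the recovered reads was the count-model alternative. Both were tested on simulated data of 19821 genes for the genotype effect, with an assumed dispersion of 0.05: 100% of the 100 genes changed by 2 log2 units and of the 100 changed by 3 were recovered, with 11 false calls by limma and 10 by edgeR. This checks the scripts and does not describe the power in these data. p-values measure the spread between these libraries of pooled RNA.

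Correlations between treatments of 1 genotype share its control library. They are set beside 100 simulations with no treatment effect, made with the residual spread of the additive fit. That spread includes the genotype-by-treatment difference, so the simulated overlaps and covariances may be too large for noise alone. Gene spans of the 4-fold lists were compared with 10000 random lists matched on mean expression in 20 bins.

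Alternatives fixed before the data were examined were a pseudocount of 2 or 50, no filter or a floor of 100, median-of-ratios scaling, a 2-fold rule, limma without the trend or without the treatment term, edgeR, and leaving out the 2 libraries of each condition in turn. Averaging both control libraries, setting libraries under 3 reads to 3 and the test of splits were added after seeing the data. Median-of-ratios scaling would shift single libraries by -0.35 (KO ABA) to 0.47 (WT dehydration) log2 units against the deposited scaling. No column was left unused. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, R 4.3.3, limma 3.58.1 and edgeR 4.0.16 were used.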

Results

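Transcript levels were measured in 8 libraries of moss protonemata, 1 for each of 4 conditions in WT and in the PpanrKO line (KO). The series title describes the targeted gene as an ABA response regulator of basal land plants needed to acquire desiccation tolerance. ABA (abscisic acid) is the plant hormone of water stress, and mannitol in the medium draws water from cells by osmosis. Total reads per library were 26126876 (WT control), 29960046 (WT ABA), 36119189 (WT mannitol) and 22516957 (WT dehydration). In KO they were 32889911, 38767634, 35622143 and 27245734 in the same order. With 1 library of pooled RNA per group, the differences between 2 libraries have no replicate check, and fold intervals in brackets are 95% counting intervals.

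The deposited IDs carry no names, so reads of the targeted gene are not given here as a check of the labels. Picked by the WT and KO labels after their values were seen, 2 genes had at least 100 reads in every WT library and at most 3 in every KO library. No gene showed the reverse. Since the labels did the picking, these genes are no check of the labels. Phpat.001G140500 (build V3.0, chromosome 1, 24268835 to 24275759, minus strand) had 471, 367, 898 and 106 reads in WT control, ABA, mannitol and dehydration. It had 0, 0, 0 and 1 in the KO libraries, which puts the KO control at least 137-fold lower with 3 reads as the floor. Phpat.001G042900 (chromosome 1, 7528180 to 7530060, plus strand) had 499, 780, 139 and 294 reads in WT and 3, 0, 0 and 0 in KO. Neither is identified here as the targeted gene.

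The first question was how the transcriptome answers ABA and what of that answer is left in KO. In WT after 1 h of ABA, 1288 of 19821 genes were at least 4-fold higher than in the control and 649 were lower. The largest differences were in Phpat.003G020700 (chromosome 3, 3474482 to 3475488, minus strand) and Phpat.003G020500 (chromosome 3, 3452459 to 3453465, plus strand). Phpat.003G020700 had 11 reads in the control and 189290 after ABA, 28822-fold higher (16108 to 57738), and Phpat.003G020500 had 11 and 189279. Their counts were equal or nearly equal in every library. After ABA they were closer than a random split of reads between copies would be likely to leave. The same reads may therefore be counted at both genes, and the 2 may be the same signal. Phpat.027G009300 (chromosome 27, 1324996 to 1329780, minus strand) was 1049-fold lower (509 to 2610), with 12301 reads in the control and 7 after ABA. Phpat.015G043500 (chromosome 15, 7020834 to 7022400, minus strand) was 183-fold lower (134 to 258).

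In KO the same treatment left 171 genes 4-fold higher and 262 lower. The genes 4-fold higher in WT had a median log2 response of 3.25 there and 0.13 in KO, where the median of all genes was 0.23. Of these 1288 genes, 171 (13.3%) were at least 2-fold higher in KO and 35 at least 4-fold. Phpat.003G020700 went from 32 reads in the KO control to 2 after ABA. Of the 649 genes lower in WT, 248 (38.2%) were at least 2-fold lower in KO, with a median of -0.68. Phpat.027G009300 was 4561-fold lower in KO (1781 to 16740), and Phpat.005G084800 (chromosome 5, 16084219 to 16086142, plus strand) was 517-fold lower (322 to 887).

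Phpat.020G086400 (chromosome 20, 15254125 to 15256726, plus strand) was 32.3-fold higher with ABA in KO (28.4 to 37.0) and 39.3-fold higher in WT (33.2 to 47.0). Phpat.016G097200 (chromosome 16, 16148924 to 16152439, minus strand) had 1 read in the KO control and 505 after ABA, a ratio of 433 (77.3 to 17121), against 0 and 9 in WT. Picked in KO and read in WT, genes 4-fold higher had a WT median of 0.29, and genes 4-fold lower had -1.63. Across genes, which are not independent replicates, the WT and KO responses to ABA correlated with Pearson's r = 0.13 and Spearman's rho = 0.12. The KO split with median-of-ratios scaling was 119 higher and 320 lower.

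**Figure D1:**
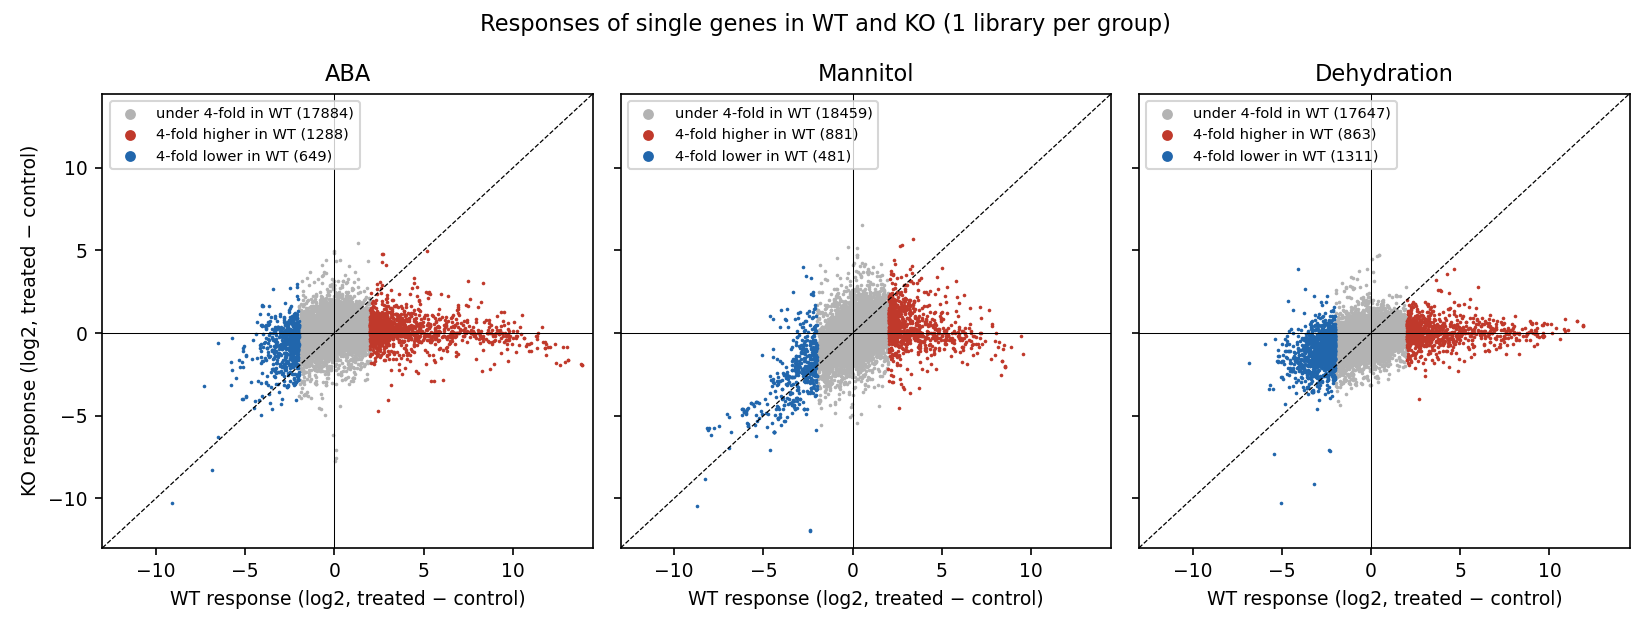
Response of each of 19821 genes in KO (vertical axis) against WT (horizontal axis), as log2(normalized reads + 10) of the treated library minus the control of the same genotype, with 1 panel per treatment; the dashed line marks equal responses. Red points are genes 4-fold higher in WT and blue points genes 4-fold lower; the red points lie along a KO response of 0 for ABA (median 0.13) and dehydration (median 0.01), while the blue points for mannitol follow the dashed line more closely (median -2.24).

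Dehydration to 70% fresh weight loss asked the same question of drying itself. In WT, 863 genes were at least 4-fold higher and 1311 lower. The 2 largest differences were again Phpat.003G020700, with 11 reads in the control and 63193 after dehydration (7329-fold, 4096 to 14682), and Phpat.003G020500, with 63188. Phpat.018G010400 (chromosome 18, 2599494 to 2603068, plus strand) was 166-fold lower (104 to 286), with 3605 reads in the control and 17 after drying. Phpat.016G027000 (chromosome 16, 4402291 to 4405811, plus strand) was 83.9-fold lower in WT (55.3 to 134), and in KO it had 2651 reads in the control and 1960 after drying.

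In KO 57 genes were 4-fold higher and 359 lower after dehydration. The 863 genes higher in WT had a median log2 response of 3.30 in WT and 0.01 in KO, where 76 of them (8.81%) were at least 2-fold higher and 9 at least 4-fold. Of the 1311 genes lower in WT, 682 (52.0%) were at least 2-fold lower in KO, with a median of -1.04 against -0.25 for all genes. Phpat.027G009300 (15628 reads in the KO control and 4 after drying) and Phpat.005G084800 (7524 and 5) had the lowest values. The highest were Phpat.001G043100 (chromosome 1, 7536666 to 7538187, minus strand) and Phpat.1Z039500 (scaffold_38, 75687 to 77208), each with 1 read in the KO control and 297 after drying. Their counts were equal in all 8 libraries, as in copies that share reads, and both values are uncertain.

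Genes picked in KO and read in WT had medians of -0.24 (57 higher) and -2.28 (359 lower) after dehydration. The WT and KO responses correlated across genes with r = 0.37 and rho = 0.40. Median-of-ratios scaling gave a KO split of 89 higher and 255 lower.

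Of the 3 treatments, 1 h of mannitol had the highest share of genes picked in WT that were at least 2-fold in the same direction in KO. In WT, 881 genes were at least 4-fold higher and 481 lower, and in KO 291 were higher and 592 lower. Phpat.008G061400 (chromosome 8, 10927107 to 10929876, minus strand) was 1409-fold higher in WT (806 to 2727), with 12 reads in the control and 21467 with mannitol, and had 20 and 5 reads in KO. Phpat.008G073700 (chromosome 8, 12919565 to 12920833, plus strand) had 4 and 12600 reads in WT and 1 and 0 in KO. Phpat.027G009300 was 651-fold lower in WT (437 to 1016) and Phpat.005G084800 was 515-fold lower (333 to 844), with log2 differences of -10.48 and -8.81 in KO.

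Of the 881 genes higher with mannitol in WT, 239 (27.1%) were at least 2-fold higher in KO, with a median of 0.26 there against 2.80 in WT. Of the 481 lower genes, 380 (79.0%) were at least 2-fold lower in KO, with a median of -2.24 against -2.84 in WT. In KO the lowest values were in Phpat.006G060600 (chromosome 6, 10934034 to 10935973, minus strand), with 145375 reads in the control and 41 with mannitol, 5550-fold lower (4091 to 7735), and Phpat.006G060700 (chromosome 6, 10939288 to 10940656, plus strand), 5741-fold lower (4021 to 8510). In WT, Phpat.006G060600 was 5.32-fold lower (5.27 to 5.37). The highest KO values were in Phpat.018G062000 (chromosome 18, 13259200 to 13262275, plus strand), 175-fold (94.8 to 365), and Phpat.016G097200, with 1 read in the control and 798 with mannitol (a ratio of 510, 91.2 to 20161).

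Picked in KO and read in WT, the medians with mannitol were 0.97 (291 higher) and -1.88 (592 lower), and the responses of the genotypes correlated across genes with r = 0.46 and rho = 0.41. Of the genes 4-fold lower in KO, 68.1% were at least 2-fold lower in WT with mannitol and 80.8% with dehydration. Under median-of-ratios scaling 567 genes were higher and 739 lower in WT.

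**Figure D2:**
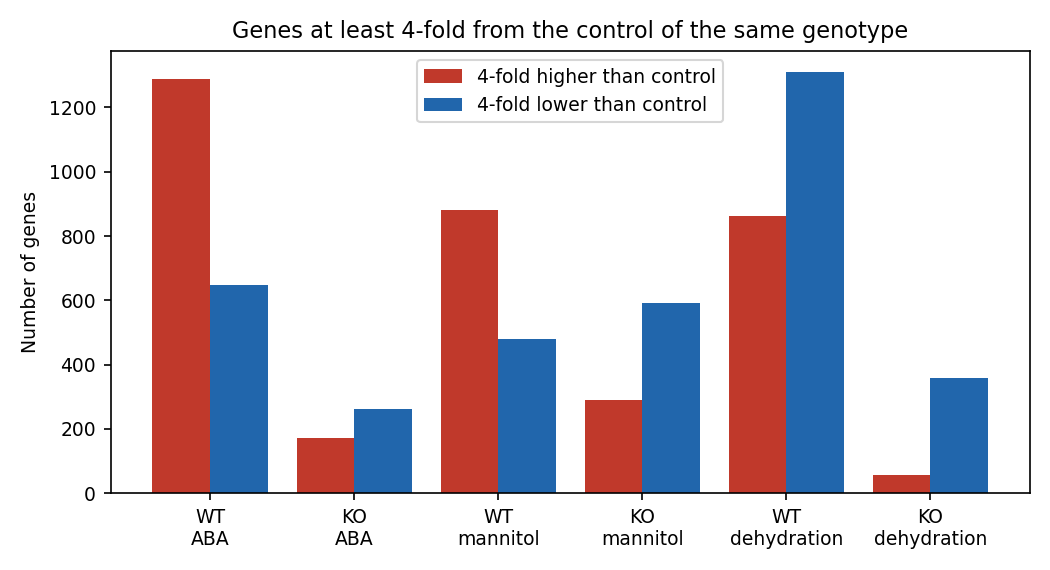
Number of genes (vertical axis, from 0) at least 4-fold higher (red) or lower (blue) than the control library of the same genotype, for each treatment in WT and KO; each bar is a count from 1 pair of libraries and has no error bar. In WT 1288 genes were higher after ABA and 863 after dehydration, against 171 and 57 in KO.

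Within WT the answers to ABA and to dehydration overlapped most. Of the 863 genes 4-fold higher after dehydration, 780 (90.4%) were also 4-fold higher after ABA, where independent lists would share 56.1. Simulated treatments without effect shared 54.8, with a spread that also holds the genotype-by-treatment difference. That value is no pure noise level, since in KO only 17 higher genes were shared by ABA and dehydration. ABA and mannitol shared 584 higher genes (57.2 for independent lists), and 498 genes were higher under all 3 treatments. Of those 498 genes, 5 were at least 2-fold higher in KO under all 3 treatments. Of 160 genes 4-fold lower under all 3 treatments in WT, 98 were at least 2-fold lower under all 3 in KO. The ABA and dehydration responses correlated across genes with r = 0.88 (simulated 0.50) and a covariance of 1.87 (simulated 0.26). For ABA and mannitol r was 0.62 with a covariance of 1.06, and for mannitol and dehydration 0.59 with 0.96. Each genotype has 1 control library, so part of the excess may come from the shared control, and with 1 of the 2 treatments taken against the KO control r was 0.80 or 0.81 for ABA and dehydration, 0.48 or 0.63 for ABA and mannitol, and 0.45 or 0.61 for mannitol and dehydration.

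Compared directly, the genotypes differed least in the control condition. There, 179 genes were 4-fold higher in KO and 167 lower, and the 2 control libraries correlated across genes with r = 0.95. Phpat.002G032200 (chromosome 2, 4798138 to 4800447, plus strand) was 146-fold higher in KO (73.6 to 338) and had 8, 2, 20 and 1 reads in WT control, ABA, mannitol and dehydration against 1019, 828, 1510 and 1143 in KO. Phpat.026G025700 (chromosome 26, 3672772 to 3675034, minus strand) was 47.8-fold higher (43.9 to 52.1). Phpat.026G007800 (chromosome 26, 776337 to 777519, minus strand) was 141-fold lower in KO (96.1 to 216), and Phpat.011G015300 (chromosome 11, 2385571 to 2387273, minus strand) had 1417 reads in WT and 3 in KO, with 2 other genes of nearly equal counts. The median-of-ratios split was 97 higher and 241 lower.

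After ABA 1376 genes were 4-fold higher in KO than in WT and 1271 lower, and after dehydration 1241 and 1109. The lowest after ABA were the neighbours Phpat.003G115800 (chromosome 3, 20194227 to 20195536, minus strand), with 177526 reads in WT and 0 in KO (at least 101203-fold lower), and Phpat.003G115900 (chromosome 3, 20196645 to 20197899, minus strand), with 172773 and 0. The highest were Phpat.017G064400 (chromosome 17, 11841714 to 11843147, plus strand), with 0 reads in WT and 3021 in KO (at least 589-fold higher), and Phpat.026G025700, 258-fold higher (226 to 297). After dehydration Phpat.026G025900 (chromosome 26, 3772319 to 3775495) and Phpat.026G025800 (chromosome 26, 3751006 to 3753278) were the highest in KO, the former by 873-fold (488 to 1750) and the latter with 9 reads in WT and 11236 in KO. Both lie near Phpat.026G025700, and their reads ran in parallel with it over all libraries. Reads shared by copies cannot be told apart here from separate differences. Phpat.001G151700 (chromosome 1, 26260127 to 26261936) was 8303-fold lower (3242 to 30476) and Phpat.007G055000 (chromosome 7, 8937914 to 8940722) 3357-fold lower (2124 to 5665). With median-of-ratios scaling the splits were 824 higher and 1569 lower after ABA, and 954 and 1369 after dehydration.

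With mannitol 353 genes were 4-fold higher in KO and 818 lower. Phpat.018G007000 (chromosome 18, 1915340 to 1916380, plus strand) had 0 reads in WT and 1013 in KO, at least 313-fold higher, and Phpat.005G092200 (chromosome 5, 17716009 to 17717302, plus strand) was 170-fold higher (86.2 to 395). Phpat.003G115800 had 22741 reads in WT and 0 in KO, and Phpat.009G025500 (chromosome 9, 3378066 to 3380365, minus strand) was 5897-fold lower in KO (2862 to 14668).

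**Figure D3:**
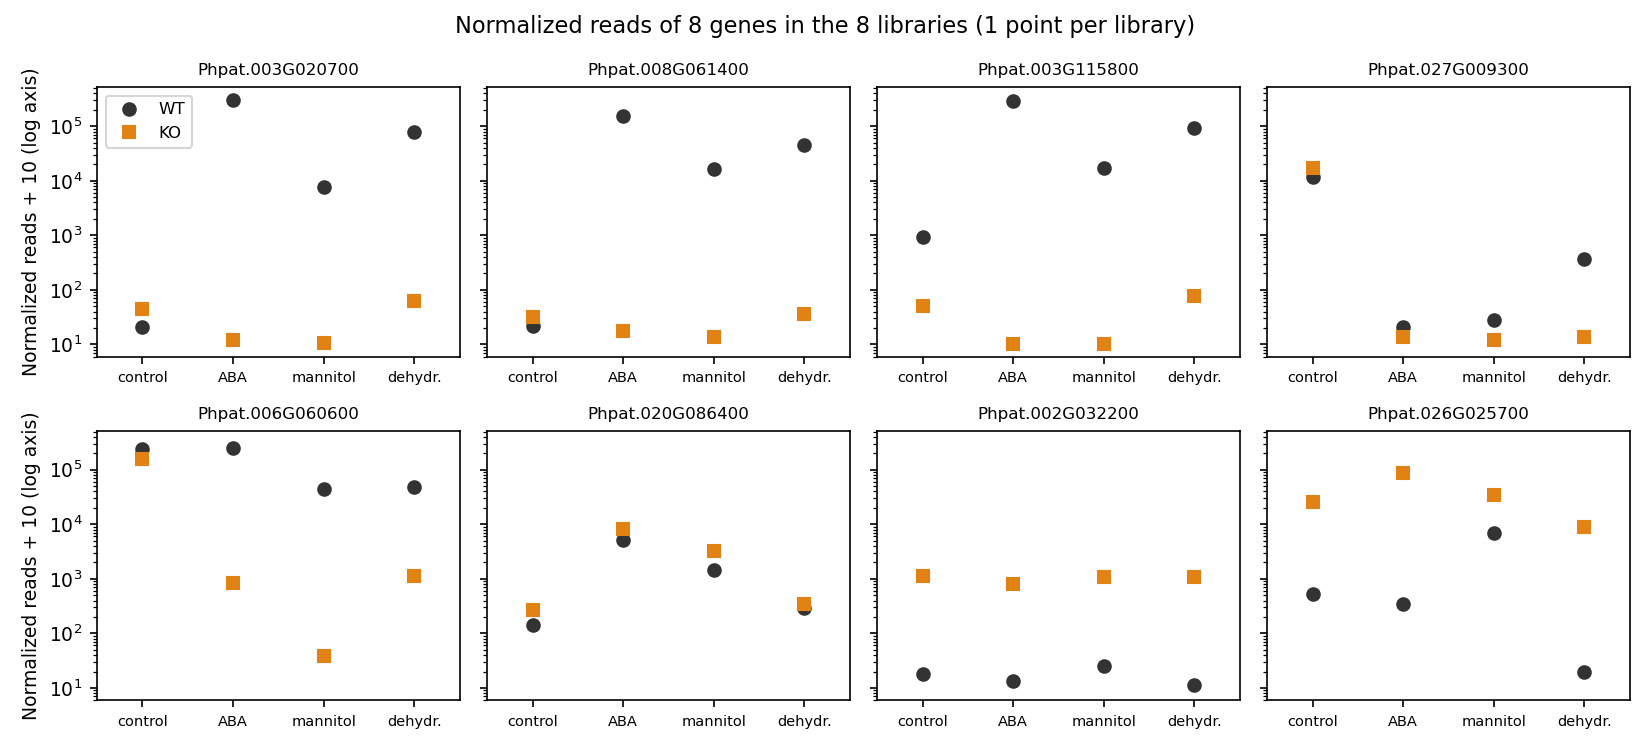
Normalized reads plus 10 (log vertical axis) of 8 named genes in each condition, with WT as black circles and KO as orange squares; each point is 1 library and there are no error bars. Phpat.003G020700 is high in the 3 treated WT libraries and low in KO, Phpat.027G009300 is lower in every treated library of both genotypes, and Phpat.002G032200 is higher in all 4 KO libraries.

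In the additive limma fit over all 8 libraries, 741 genes were higher and 332 lower in KO across the 4 conditions at an adjusted p under 0.05. Phpat.026G025700 rose by 6.17 ± 1.03 log2 units (SE, limma adjusted p = 0.037) and Phpat.026G026100 (chromosome 26, 3841304 to 3843939) by 6.12 ± 1.02 (limma adjusted p = 0.037), each higher in 4 of 4 conditions. The reads of these 2 genes ran in parallel over the 8 libraries, with 22857 and 21269 in the KO control and 92800 and 86418 in KO ABA. Reads shared by copies cannot be told apart here from separate effects. Phpat.003G115800 fell, with a log2 difference of -10.02 ± 1.51 (limma adjusted p = 0.030), as did Phpat.003G115900, with -9.88 ± 1.56 (limma adjusted p = 0.033), each lower in 4 of 4. For Phpat.003G115800 the difference was -4.25 in the control, -14.81 with ABA, -10.76 with mannitol and -10.25 with dehydration. Its average therefore also holds the genotype-by-treatment difference, which was not tested. All 4 of these genes kept their direction but missed the threshold with edgeR (adjusted p 0.062 to 0.076), without the filter, and without the ABA, mannitol or dehydration libraries (adjusted p up to 0.17 over the settings), and Phpat.026G025700 and Phpat.026G026100 missed it without the treatment term too (adjusted p 0.052 for both). edgeR called 554 higher and 364 lower, and 789 genes were called in the same direction by both tools. With median-of-ratios scaling the split was 319 higher and 309 lower. Without the 2 libraries of 1 condition the count was 2439 (control left out), 0 (ABA, with 3529 genes at an unadjusted p under 0.05), 5 (mannitol) and 25 (dehydration), and without the filter limma called 0 (6750 unadjusted), so the count rests on single conditions and settings.

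Of the effects shared by both genotypes, mannitol had 3 genes higher and 107 lower with limma, against 7 and 59 with edgeR. Phpat.019G046400 (chromosome 19, 8955616 to 8957835) fell, with a log2 difference of -7.04 ± 0.57 (SE, limma adjusted p = 0.017), and Phpat.027G009300 with -9.60 ± 1.14 (limma adjusted p = 0.032), each in both genotypes. Phpat.003G044800 (chromosome 3, 8197947 to 8200936) rose by 4.48 ± 0.56 (limma adjusted p = 0.039) and Phpat.020G086400 by 3.48 ± 0.30 (limma adjusted p = 0.018), again in both. For ABA, limma called 1 gene, Phpat.020G086400, higher by 5.08 ± 0.30 (adjusted p = 0.036), with 2556 genes at an unadjusted p under 0.05, and edgeR called 0 (2446 unadjusted), as did limma without the filter, without the trend and with median-of-ratios scaling. For dehydration limma and edgeR both called 0 genes, with 2826 and 2788 at an unadjusted p under 0.05. Without the filter limma called 0 genes for mannitol too (4502 unadjusted), and with edgeR Phpat.027G009300 (adjusted p = 0.10, with 0.021 to 0.16 over the settings) and Phpat.003G044800 (0.076, with 0.035 to 0.16) missed the threshold for mannitol.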

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

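All tests below on the loss of the WT response in KO were chosen only after that result was seen, whereas those on the difference between higher and lower genes were set before their results were seen.

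Of the named genes, 7 moved in opposite directions in WT and KO by at least 2-fold each under the same treatment. These differences were not tested, since each rests on 1 library per group. The genes were named for extreme differences, which favours such opposites. Among all genes, 167 were 2-fold higher in WT and lower in KO with ABA and 138 the reverse, against 376 higher and 469 lower in both. With mannitol these counts were 161 and 63 against 771 and 778, and with dehydration 112 and 63 against 133 and 1313. Phpat.003G020700 and Phpat.003G020500, of nearly equal counts, may be the same signal. Phpat.003G115800 and Phpat.003G115900, whose reads ran largely in parallel, may share reads too. The KO minus WT difference of the ABA response on the log2 scale was -15.79 for Phpat.003G020700 and -15.79 for Phpat.003G020500, -10.56 for Phpat.003G115800, -10.89 for Phpat.003G115900 and -10.81 for Phpat.009G025500. For mannitol it was -10.64 for Phpat.003G020700 and -10.64 for Phpat.003G020500, -10.81 for Phpat.008G061400, -6.50 for Phpat.003G115800, -6.82 for Phpat.003G115900 and -10.86 for Phpat.009G025500. Phpat.026G007800 moved the other way with mannitol, lower in WT and higher in KO, with a difference of 3.13. For dehydration the difference was -9.60 for Phpat.009G025500. All were low in the KO control, at 20 to 69 reads. Phpat.026G007800 counted 107 reads in KO with mannitol, and the others 0 to 27 in KO under the treatments just named for each.

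The genes that ABA and dehydration put 4-fold higher in WT were near their control level in KO. With median-of-ratios scaling the larger of the 2 KO medians was 0.21 log2 units. That test could not decide on scaling, since it shifts single libraries by only -0.35 to 0.47 log2 units. Under the deposited scaling the KO medians were 0.13 (ABA) and 0.01 (dehydration), against 0.23 and -0.25 for all genes. A factor per library shifts all genes about alike, so it would not set these genes apart from the rest. A single wrong or untreated library of the 2 treated KO libraries is argued against. The other one should then respond, and the larger of the medians under the deposited scaling was 0.13. Both medians share the KO control library, so they cannot speak to a wrong KO control. The treated libraries compared directly can, because the KO control does not enter. There the picked genes had a median KO minus WT difference of -3.21 (ABA) and -3.78 (dehydration) log2 units. This argues against a wrong KO control as the sole cause for these genes, although they were picked for high values in treated WT. In the controls the picked genes had a median KO minus WT difference of 0 (ABA) and -0.11 (dehydration) log2 units. The KO libraries were not shallower: the lower of the ratios of KO to WT reads was 121%. Whether the loss comes from the targeted gene or from something else in this 1 line stays open. A dependence of these genes on the targeted gene is a hypothesis that the median of 0.13 does not contradict.

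Genes 4-fold lower in WT were 2-fold lower in KO more often than genes 4-fold higher were higher, by 24.9 percentage points for ABA (10.2 with the 2-fold rule to 41.4 over the settings), 51.9 for mannitol (40.3 to 71.7) and 43.2 for dehydration (25.6 to 52.7). Among all genes, 4.97% were 2-fold lower and 8.29% higher in KO with ABA, 9.56% and 9.10% with mannitol, and 10.8% and 1.97% with dehydration, so 8.82 points of the dehydration gap are also found in all genes. With median-of-ratios scaling the smallest gap was 30.5 points, which argues against the choice between these 2 scalings as the cause. Transfer onto soaked paper is argued against as the sole cause, because the 262 genes 4-fold lower in KO ABA had a median WT response of -2.09 to dehydration, where tissue was not put on soaked paper. Other handling shared by all 3 treatments, such as moving the tissue, stays open because no mock-treated library was analysed here, as does the hypothesis that a part of the decrease does not need the targeted gene.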

How the results depend on the processing

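The settings in this part were fixed before the data were examined, except averaging the 2 control libraries, the floor of 3 reads and the test of splits, which were added after. The cause of a move was not tested.

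The sums of genes 4-fold higher and lower were within 1.5 times of the sum in the report with no filter, a floor of 100, median-of-ratios scaling and averaged controls. Single directions moved further: genes higher went from 291 to 171 (KO mannitol) and from 353 to 210 (KO against WT, mannitol) with a floor of 100, from 57 to 98 (KO dehydration) with averaged controls, and with median-of-ratios scaling as in the report. WT ABA had 319 lower (from 649) with a pseudocount of 50, and KO ABA had 276 higher (from 171) with a pseudocount of 2. With a pseudocount of 2, KO dehydration gave 646 genes and KO against WT in control 559. With a pseudocount of 50, which pulls low genes toward 0, counts were 877 (WT mannitol), 1344 (WT dehydration), 240 (KO ABA), 525 (KO mannitol), 187 (KO dehydration), and for KO against WT 145 (control), 741 (mannitol) and 1474 (dehydration). That pseudocount turned the larger direction in WT dehydration (707 higher, 637 lower) and in KO against WT after ABA (731, 1039) and dehydration (638, 836). The 2-fold rule admits more genes: 5497, 5520 and 6125 in WT and 2629, 3699 and 2528 in KO for ABA, mannitol and dehydration, and 2449, 7710, 3475 and 6869 for KO against WT in control, ABA, mannitol and dehydration. It turned KO ABA to 1644 higher and 985 lower.

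The median KO response of genes higher in WT stayed under 0.5 log2 units in every setting. For ABA it was 0.071 (pseudocount 50), -0.0169 (median-of-ratios) and 0.23 (2-fold rule). For mannitol it was 0.44 (pseudocount 2), 0.0202 (pseudocount 50), 0.14 (floor 100), 0.00 (median-of-ratios) and 0.39 (2-fold rule), and for dehydration 0.21 (median-of-ratios). With libraries under 3 reads set to 3 and no pseudocount it was 0.12 for ABA, 0.34 for mannitol and -0.07 for dehydration. The correlations between genotypes moved little: ABA 0.11 (pseudocount 2), mannitol 0.42 (pseudocount 2), 0.48 (pseudocount 50), 0.44 (no filter) and 0.47 (floor 100), and dehydration 0.34 (pseudocount 2) and 0.39 (pseudocount 50).

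The tested counts depended on the setting most. The genotype effect gave 0 genes without the filter, 628 with median-of-ratios scaling, 700 without the treatment term, and from 0 to 2439 when the libraries of 1 condition were left out (more lower than higher without control, mannitol or dehydration). The ABA effect gave 2 genes with a pseudocount of 50 and 0 without the filter, with median-of-ratios scaling, without the trend and with edgeR (2104, 2417 and 2446 genes at an unadjusted p under 0.05 for the last 3). The mannitol effect gave 0 without the filter and 66 with edgeR, and dehydration 1 with a pseudocount of 50. Without the filter limma had 6750, 3130 and 4502 genes at an unadjusted p under 0.05 for genotype, ABA and mannitol; edgeR was run only with the filter.

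Of the 35 splits of the 8 libraries into 4 and 4, 3 gave at least as many genes as the real split (1073), and 3 could not be fitted. Under the treatment term the 2 other splits (3211) are the same fit, of WT against KO in the ABA and dehydration pairs, which points to a structure of the samples. Only the 8 splits that part every pair keep the pairing, and they are too few for a share under 0.05; the highest other of them gave 0.

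No named gene reversed. Of its values under the settings, 148 kept their side of the threshold or stayed within counting error, 47 moved further and 32 lost the adjusted threshold. Adjusted p over the settings ran from 0.0017 to 0.17 for the 4 genes named for genotype, from 0.016 to 0.16 for those named for mannitol and from 0.023 to 0.21 for Phpat.020G086400 with ABA. The fixed gene lists were not run.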

Other observations

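The mannitol response of WT divided into parts that differed in KO, in a division chosen after the data were seen. Of the 881 genes 4-fold higher with mannitol in WT, 584 were also 4-fold higher with ABA. In KO these had a median mannitol response of -0.02 log2 units, and 12.3% were at least 2-fold higher. The 163 genes that ABA moved by under 2-fold in WT had a KO median of 1.41, and 63.8% were at least 2-fold higher. Their median response to ABA in KO was 0.84, against 0.23 for all genes, so in KO they were not apart from ABA. The 115 genes between had 0.89 and 44.3%. Genes 4-fold lower with mannitol showed no such division, with 80.6% (196 genes also lower with ABA), 71.6% (109) and 76.5% (119) at least 2-fold lower in KO. In both directions, genes that ABA moved at least 2-fold the other way in WT were left out of these classes. The division was smallest with the 2-fold rule, with KO medians of 0.15 (also ABA) and 0.51 (under 2-fold with ABA). A pseudocount of 50 gave -0.06 and 0.91, and the other settings -0.14 to 0.00 and 1.21 to 1.52.

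Genes answering ABA in WT also lay next to each other. The longest run was of 9 consecutive genes past the floor on chromosome 3 (3410948 to 3518323), with a median log2 response of 13.10 in WT and -1.65 in KO. Together they held 858164 reads in WT ABA and 10 in KO ABA. The run includes Phpat.003G020700 and Phpat.003G020500, with 189290 and 189279 reads in WT ABA and equal or nearly equal counts in every library. These totals were not corrected for reads counted at both genes, so they are not totals of separate reads. A run of 6 genes lay on chromosome 20 (4419216 to 4479014), with medians of 3.22 in WT and 0.06 in KO. In all, 34 runs of at least 3 genes held 117 of the 1288 genes.

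The runs themselves were not tested, but neighbouring pairs were, by tests set before their results were seen. Among 19755 neighbouring pairs, 226 had both genes 4-fold higher with ABA in WT, against a median of 85 in 10000 permutations within bins of mean expression (one-sided permutation p = 0.0001, the smallest they can give). Without pairs that overlap or have near-equal counts, 181 were left against 78 (one-sided permutation p = 0.0001). Overlapping neighbours and neighbours of near-equal counts therefore do not account for the whole. Sequences were not compared, so neighbouring copies that share reads unequally were not excluded. More distant copies could share reads too. Regulation of neighbours together, or tandem copies that keep their regulation, is a hypothesis and was not tested apart.

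Of the 12 lists of 4-fold genes by treatment, genotype and direction, 10 had a median span below the central 95% of the random lists. The lists of 1 genotype share a control library and many genes, so they are not separate results. In WT, 780 of the 863 genes higher with dehydration were also in the ABA list. In KO, 205 of the 262 genes lower with ABA were also in the mannitol list. The median span from start to end, introns included, was 2771 bases for the genes higher with ABA in WT against 3152 in random lists matched on expression. It was 2055 against 2795 for those lower with mannitol in WT and 1997 against 2853 for those lower with dehydration in KO. The genes higher in KO with ABA (2567, central 95% from 2521 to 3113) and with mannitol (2447, 2415 to 2841) lay inside it. Spans of coding sequence were not analysed here.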
